A study of Metallosphaera sedula with 3 samples.

How the data were processed

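RNA of the thermoacidophilic archaeon Metallosphaera sedula (strain DSMZ 5348) was compared between 3 conditions on 3 two-colour spotted slides. Per the labels, day 0 was the inoculum, grown on H2 and CO2 without mineral and harvested 1 day after its last transfer, and days 3 and 9 were cultures 3 and 9 days after transfer onto 10 g/L chalcopyrite, a copper iron sulfide. All were grown at 70 °C and pH 2 with 28% H2, 7% CO2 and 14% O2 in the headspace. Each condition was 1 RNA pool from several cultures. One portion of it was labelled with Cy3 and another with Cy5, and they were put on different slides, so the slides closed a loop: day 3 (Cy3) with day 0 (Cy5), day 9 (Cy3) with day 3 (Cy5), and day 0 (Cy3) with day 9 (Cy5).

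The deposited scanner tables give, per the file headers, the median and mean foreground intensity of each spot, the local background intensity and the percent of saturated pixels, in both channels, with no normalization. Channel 1 was read as Cy3 and channel 2 as Cy5, per the labels. The scanner and its software are not given in the sources used here. Each slide held 11640 probe spots, 5 for each of 2328 probes, and 3912 spots named empty. All 5 spots of a probe lay in 1 print block. The authors' deposited value table holds log2 values for part of the probes, and how it was made is not given in the sources used here. Each of its values is a sign times the log2 of a number with 1 decimal. Set against the slides, that number matched the size of the log2 fold change, so the table was read as holding the log2 of a log2 fold change, with its sign turned to give later minus earlier day. A value of 0 took its side from whether a minus sign was written before it. The table's scale and direction were thus found from the slides and are not stated by the authors, and its centring is unknown. The medians of its columns as deposited were 0 for day 0 over day 3, 0.14 for day 3 over day 9 and 0 for day 0 over day 9.

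The files pair no probe with a gene name. Of the probes, 2258 carry plain numbers between 1 and 2296, and 70 carry other names. The numbers were read here as Msed locus numbers, a reading taken from the files and not stated by them. It rests on 11 further probes whose names contain Msed and a locus number. Their fitted differences lay closer to the probe with that number (mean distance 0.719 on the log2 scale) than random pairings did (median 1.45, permutation p = 0.0012 over 10000 draws). The 11 probes cover 9 loci, and the draws treated probes that share a locus as independent. A wrong reading would change every gene name below and none of the values. Functions are background knowledge attached to locus tags listed before the data were examined, as were the tests, the thresholds and the lists. Outside those lists at most 2 rising and 2 falling loci are printed per comparison.

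Median foreground was corrected with normexp (offset 50), fitted on all spots, and normalized by loess within each slide with empty spots at weight 0, in limma 3.58.1 under R 4.3.3. The 5 spots of a probe were averaged. The 3 log2 ratios of a probe were fitted with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg over 2328 probes) with coefficients for days 3 and 9 against day 0, so that a dye effect cancels in each difference. A probe was called where the adjusted p was under 0.05 and the difference at least 2-fold. One residual degree of freedom per probe remained, joined by 7.17 prior degrees of freedom. The p-values compare RNA pools and measure slide and labelling error, not the spread between cultures. In simulated data with 200 of 2328 probes changed between days 0 and 3, the fit called 62.8% of those changed by 1.5 on the log2 scale, 92.4% at 2, and 99.6% at 3 and at 4. Of its calls there, 6.24% were false, slightly above the nominal share. Days 3 and 9 were simulated without a difference, and the fit made 26 calls between them over 5 simulations.

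The rule for named genes, fixed at the same time, took per comparison the 10 highest and 10 lowest called probes above background on both slides of at least 1 of the conditions compared, up to 4 members with the largest difference from each gene list, and 8 fixed loci. Members named in a count of 5 or fewer outside that rule were chosen after their values were seen, and so were the sub-blocks of lists. The 5 lists defined by locus tags were used. The 19 lists defined by product names were not used, because the files give no product names. A list's median was set against 10000 random lists matched on intensity, as a description of these pools. The random lists hold scattered genes, while all lists but that of CO2 fixation are runs of neighbouring genes. Neighbours changed alike in part, so the random range is too narrow for those lists.

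By the detection rule fixed beforehand (background plus 2 SDs in at least 3 of 5 spots) nearly all probes passed, but so did 67.2% to 100% of the empty spots, so the rule separates little. A stricter rule, the 95th percentile of the empty spots, was added after seeing the data. By it, 1079 probes stood above the empty spots on both slides of every condition and 384 on neither slide of some condition. A probe counted as saturated in a channel where at least 3 of its 5 spots were at the top scanner value, as 219 probes were in at least 1 channel. The setting without saturated probes was stricter: it left out the 393 probes with any saturated spot and kept 1935. A probe saturated on both slides of its brighter condition, or not above the empty spots in its dimmer one, is given as "at least N-fold" from channel means after loess and Aquantile only where that value lies below the fitted fold. Channel means, unlike the fit, compare across slides, and where they exceeded the fitted fold, the fitted log2 difference is given with the limit named. Saturated spots short of this, on 1 slide or in fewer of a probe's spots, are mostly not marked below. The number of slides limits the precision: the median standard error was 0.303 on the log2 scale.

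Alternatives covered background, offset, normalization, dim, flagged and saturated spots, spot averaging, the unit and variance model of the test, each slide left out in turn, and the authors' table.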

Results

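The transcriptome of M. sedula was followed from growth on H2 and CO2 (day 0) to 3 and 9 days on chalcopyrite with H2 supplied in the headspace. The sources used here give no reading of the remaining H2. The question was which genes differ on the mineral when this gaseous electron donor is also supplied. No culture without mineral was sampled at day 3 or day 9, so the mineral cannot be told apart from the time since transfer. The RNA was hybridised to 3 slides and each condition was measured on 2 of them, in opposite dyes. Median probe intensity ran from 607 to 2202 per channel, against medians of 13 to 496 for empty spots. The day 3 and day 0 slide had the brightest empty spots, and 57.9% to 58.8% of its probes exceeded their 95th percentile, against 87.2% to 99.8% in the channels of the other slides. Differences are given as later minus earlier day, opposite to the order in the study's sample titles. All signs rest on channel 2 holding the Cy5-labelled RNA; exchanged channels would turn every one.

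Around the loop the 3 log2 ratios of a probe should sum to 0, apart from error and any dye effect particular to that probe. The sums had a median of 0.16 and an SD of 0.74 over 2328 probes. Across probes, which are not independent replicates, the direct ratio correlated with the route over the other slides at r = 0.785 for days 0 and 3, 0.579 for days 3 and 9, and 0.789 for days 0 and 9.

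**Figure D1:**
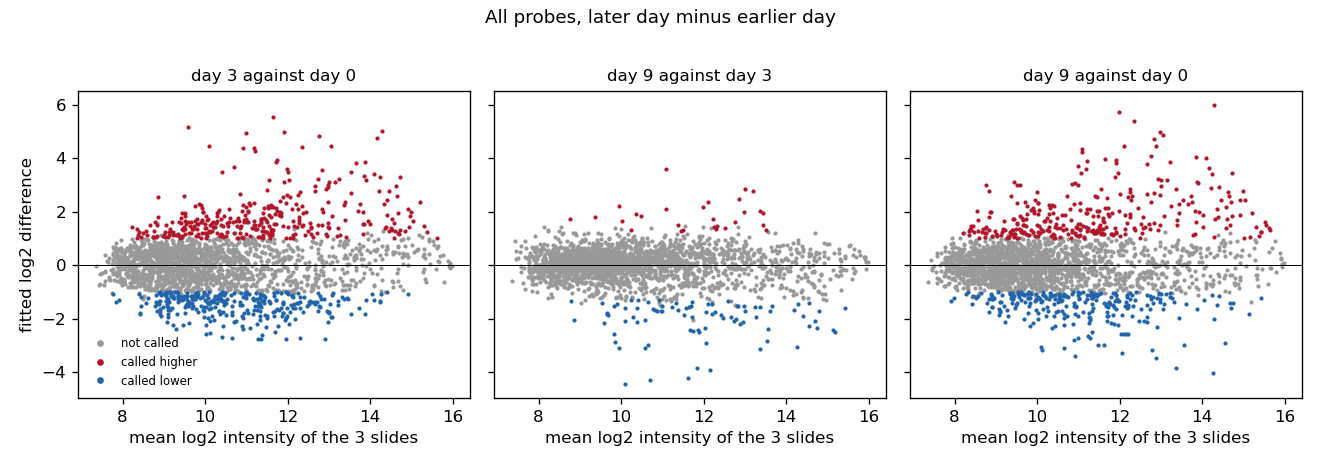
Fitted log2 difference of each of the 2328 probes (vertical axis) against its mean log2 intensity (horizontal axis), in 3 panels for the 3 comparisons, with called probes in red (higher) and blue (lower). Calls numbered 657 for day 3 against day 0, 115 for day 9 against day 3 and 572 for day 9 against day 0.

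After 3 days on chalcopyrite, 2 of 3 metal resistance genes, 2 also when adjusted over the list alone, and 11 of 20 terminal oxidase genes were higher than in the inoculum. Msed_0490 (copA), which encodes a copper-transporting P-type ATPase, rose 27.4-fold (log2 4.77 ± 0.53 SE, adjusted p = 0.00101). Its neighbour Msed_0491, saturated at day 3, rose too (fitted log2 3.28 ± 0.30 SE, adjusted p = 5.11e-04). Msed_0492 was not above the empty spots at day 3 and was not called. Msed_0490 and Msed_0491 both held saturated spots, so the size of their rise is uncertain. With saturated probes left out, only Msed_0492 of this list remained (log2 -0.33). Of the rusticyanins, blue copper proteins linked to iron oxidation, Msed_0966 rose 4.47-fold (adjusted p = 0.007) and Msed_1206 was not called (log2 0.22 ± 0.34 SE).

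Of 20 measured genes of the terminal oxidase operons, 11 rose and none fell, also when adjusted over the list alone. The list's median of 1.56 on the log2 scale lay above all 10000 matched random lists. Those hold scattered genes and are too narrow a reference for operons, whose members tend to change alike. In the soxNL-cbsAB region Msed_0504 rose 14.3-fold (log2 3.83 ± 0.31 SE), and Msed_0500, saturated at day 3, rose too (fitted log2 2.98 ± 0.30 SE). Msed_2030 and Msed_2032, in the doxBCE region, rose 9.97-fold and 5.39-fold. The authors' deposited table, read as above, gave smaller log2 differences: 2.2 for Msed_0504, 2.1 for Msed_0500, 2.8 for Msed_2030 and 2.1 for Msed_2032.

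The fox cluster, a gene set linked to iron oxidation, held calls both ways at day 3. Of its 23 genes 3 rose and 5 fell, with the same counts adjusted over the list alone. Among all 2328 probes 339 were called higher and 318 lower. The list's median of -0.34 lay within the range of -0.49 to 0.50 that holds 95% of the matched random lists. Msed_0484 (foxA, a terminal oxidase subunit) rose 3.27-fold (log2 1.71 ± 0.33 SE, adjusted p = 0.00737), Msed_0486 rose 10.7-fold and Msed_0487 rose 4.99-fold. Msed_0467 fell 4.68-fold and Msed_0477 fell 2.88-fold. Msed_0480 and Msed_0485, both saturated at day 0, fell by the fit (log2 -1.28 ± 0.29 and -1.23 ± 0.29 SE). The call of Msed_0469 rests on a probe not above the empty spots at day 3 (log2 -1.34 ± 0.31 SE), and the second probe of that locus, 2p_Msed0469, was not called (log2 -0.23 ± 0.39 SE). In the hydrogenase region, 7 of 30 genes rose and none fell, 7 also when adjusted over the list alone. Msed_0938 rose 3.92-fold and Msed_0925 rose 3.54-fold. The hydrogenase genes Msed_0944, saturated at day 0, and Msed_0945, saturated at day 3, were not called, and saturation leaves the size of their difference open.

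Of the 18 genes of the 3-hydroxypropionate/4-hydroxybutyrate cycle, which fixes CO2, 1 rose and 2 fell at day 3, and none was called when adjusted over the list alone. Msed_1424 (succinic semialdehyde reductase) rose 2.18-fold. Msed_0394 fell 2.19-fold and Msed_1993 (malonic semialdehyde reductase) fell 2.09-fold. Msed_0709 (malonyl-CoA reductase) was saturated on both days, and Msed_1321 (4-hydroxybutyryl-CoA dehydratase) was not called (log2 0.73 ± 0.32 SE). Outside the lists, Msed_1251 rose 47.2-fold, Msed_0511 rose 36-fold, Msed_2256 fell 6.87-fold and Msed_0250 fell 6.81-fold. Over all probes, 339 were called higher and 318 lower at day 3, and 684 differed at least 2-fold. With median centring in place of loess the balance turned, to 371 higher and 434 lower. At least 2-fold, it also turned without either of the slides that hold day 9 (347 higher and 398 lower). Both settings take the difference from the direct slide, so they give the same values. Without the day 3 and day 0 slide 434 were higher and 280 lower. The authors' deposited table listed 364 higher and 452 lower, and as read here every value it lists counts as at least 2-fold.

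**Figure D2:**
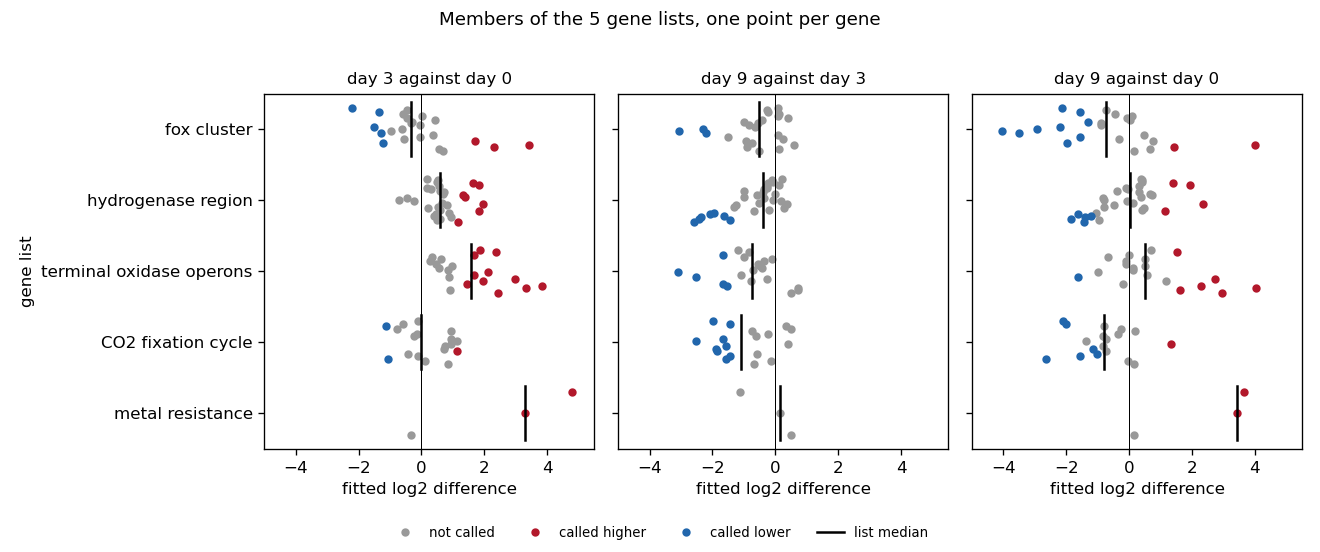
Fitted log2 difference (horizontal axis) of each member of the 5 gene lists (rows), in 3 panels for the 3 comparisons, with calls in red (higher) and blue (lower) and each list's median as a black bar. The oxidase median was 1.56 at day 3 against day 0 and -0.74 at day 9 against day 3, and the CO2 fixation median was -1.10 at day 9 against day 3.

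Between days 3 and 9, part of the genes of the hydrogenase region and of CO2 fixation fell. In the hydrogenase region 7 of 30 genes fell and none rose (10 fell when adjusted over the list alone). The 7 were Msed_0944 to Msed_0950, with Msed_0950 5.99-fold lower (log2 -2.58 ± 0.30 SE, adjusted p = 0.00504), Msed_0944 3.85-fold lower and Msed_0945, saturated at day 3, also lower (fitted log2 -2.09 ± 0.29 SE). On the day 9 and day 3 slide 6 of the 7, Msed_0944 included, had a saturated day 3 spot. The size of their fall is therefore uncertain. Of the CO2 fixation list 9 of 18 genes fell and none rose, with 9 also adjusted over the list alone, and its median of -1.10 lay below all 10000 matched random lists. Msed_0709, saturated at day 3, fell at least 3.79-fold by channel means (fitted log2 -2.52 ± 0.44 SE, adjusted p = 0.0192), Msed_1321 2.96-fold and Msed_1424 3.63-fold. Msed_0147 and Msed_1375, subunits of the acetyl-CoA/propionyl-CoA carboxylase, fell 3.92-fold and 3.70-fold.

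In the terminal oxidase operons 5 of 20 genes fell and none rose at day 9 against day 3 (7 fell when adjusted over the list alone). Msed_0322 and Msed_0324, in the soxM region, fell 8.63-fold (log2 -3.11 ± 0.29 SE) and 5.73-fold. Msed_0287 fell 3.20-fold, Msed_0503 3.15-fold and Msed_0504 2.91-fold. In the fox cluster 3 of 23 genes fell and none rose (4 fell when adjusted over the list alone): Msed_0479 8.36-fold, Msed_0478 4.89-fold and Msed_0480 4.64-fold. No member of the 3-gene metal resistance list was called, over all probes or over the list alone, and Msed_0490 stood at -1.13 ± 0.53 SE. The rusticyanins Msed_0966 (log2 0.86 ± 0.41 SE) and Msed_1206 (-1.22 ± 0.34 SE) and Msed_0484 (-0.94 ± 0.33 SE) were not called.

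Over all probes 28 were called higher and 87 lower at day 9 against day 3. Msed_1273 rose 12.2-fold. Msed_2074, saturated at day 9, rose (fitted log2 2.84 ± 0.34 SE), while Msed_1242 fell 22-fold and Msed_0812 fell 19.8-fold. The total of 115 depended on the processing: it was 56 without background correction and 232 with spots as observations and a dye term. With the dye term no error between slides is left, so that test used only the scatter of spots within slides. It called every probe at least 2-fold different. The 232 probes at least 2-fold different became 491, of which 286 were higher, without the day 9 and day 3 slide, and the CO2 fixation median moved to -0.42 over 8 members with saturated probes left out. That setting kept 1 gene of the block Msed_0944 to Msed_0950. The oxidase median of -0.74 was -1.12 in that setting, -0.40 with mean foreground, and -0.40 without the day 9 and day 3 slide, with 9 of 20 members above 0.

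At day 9 against day 0, 2 of 3 metal resistance genes were higher, 2 also when adjusted over the list alone, and so were 6 of 20 terminal oxidase genes. Msed_0490 was 12.5-fold higher (log2 3.64 ± 0.53 SE, adjusted p = 0.00239), Msed_0491 10.8-fold higher and Msed_0966 8.10-fold higher (adjusted p = 0.00172). Saturated spots of Msed_0490 and Msed_0491 leave the size of their rise uncertain here too. Of the terminal oxidase genes 6 rose, 1 fell and 13 were not called (7 rose and 1 fell when adjusted over the list alone), and the list's median of 0.50 lay within the range of -0.39 to 0.65 that holds 95% of the matched random lists. Msed_2030 rose 16.4-fold, Msed_0500 6.62-fold and Msed_0504 4.91-fold, Msed_2032, saturated at day 9, also rose (fitted log2 2.94 ± 0.30 SE), and the gene that fell was Msed_0324, 3.09-fold.

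Several fox and CO2 fixation genes were lower at day 9 than at day 0. In the fox cluster 2 of 23 genes rose and 9 fell, the same counts as when adjusted over the list alone. Msed_0486 rose 16.2-fold and Msed_0487 rose 2.67-fold. Of the genes saturated at day 0, Msed_0479 fell at least 9.69-fold by channel means (fitted log2 -4.04 ± 0.29 SE), and Msed_0480 fell too (fitted log2 -3.49 ± 0.29 SE). For Msed_0469, among the 9, the fit gave -1.57 ± 0.31 SE and its second probe, 2p_Msed0469, was not called (-0.72 ± 0.39 SE). Msed_0484 was not called (log2 0.77 ± 0.33 SE). In the CO2 fixation list 1 gene rose and 6 fell (1 and 7 when adjusted over the list alone). Msed_1993 fell 6.24-fold (log2 -2.64 ± 0.32 SE), Msed_0147 4.27-fold, Msed_0148 4.06-fold and Msed_1456 (3-hydroxypropionyl-CoA synthetase) 2.98-fold, and Msed_1220 rose 2.54-fold. The hydrogenase region split, with 4 genes higher (Msed_0924, Msed_0925, Msed_0938 and Msed_0943) and 5 lower (Msed_0945, Msed_0946, Msed_0947, Msed_0948 and Msed_0950), the same counts as over the list alone. Msed_0938 rose 5.05-fold, Msed_0948 fell 3.60-fold and Msed_0945 fell 3.07-fold.

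Over all probes 312 were called higher and 260 lower at day 9 against day 0, and 605 differed at least 2-fold. Msed_1238, saturated at day 9, rose at least 52.7-fold by channel means (fitted log2 5.99 ± 0.34 SE) and Msed_1357 rose 53.6-fold. Msed_1695, saturated at day 0, fell (fitted log2 -3.87 ± 0.29 SE) and Msed_1671 fell 10.6-fold. With median centring in place of loess the balance turned, to 321 higher and 430 lower. At least 2-fold, it also turned without the day 0 and day 9 slide (342 higher and 445 lower). Without either of the other slides 359 were higher and 233 lower, the same values in both, since both take the difference from the direct slide. The authors' deposited table listed 368 higher and 415 lower, where every listed value counts as at least 2-fold as read here. The CO2 fixation median of -0.81 ran from -1.41 to -0.52 as each slide was left out, and the fox median of -0.75 became -0.26 with saturated probes left out. The oxidase median of 0.50 became 0.12 in that setting, 0.25 with print-tip loess and 0.21 without the day 0 and day 9 slide.

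Many genes changed against day 0 on both days. Of the called probes 224 were higher and 170 lower on both, where independent lists would share 45.4 and 35.5. These comparisons share the day 0 pool, whose error can add shared calls, by an amount not estimated here. The differences correlated across probes at r = 0.793, with a covariance of 0.884. Simulated slides with no change and independent slide error gave 0.497 and 0.0669. They held no error of the day 0 pool itself, so they cannot show how much of the correlation it made. The direct slides, which carry separately labelled portions of the day 0 pool, gave r = 0.684. Of the genes higher at day 3, 41 were lower at day 9 than at day 3, where independent lists would share 12.7. Those comparisons share the day 3 pool, whose error can add to such a count, by an amount not estimated here. Their differences correlated at r = -0.337, with a covariance of -0.243. The same simulated slides, which held no error of the day 3 pool either, gave -0.504 and -0.0682.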

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

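No paired analysis was possible because each condition is 1 RNA pool. The empty-spot rule was chosen after seeing the data, the other alternatives before. Leaving a slide out leaves no residual degree of freedom, so no test, and a probe's own dye effect does not cancel. The authors' table was not run for list medians, since it lacks values for many members. The counts for day 3 and day 9 against day 0 stayed within 1.5 times the main count in every setting with a test. Aquantile and the background rule moved nothing. For day 9 against day 3, against 115 in the main setting, the count was 56 without background correction, 180 with print-tip loess, 175 without dim probes by the empty-spot rule, 213 with the median of the spots, 217 with mean foreground, 224 with slide as a random block and 232 with a dye term. The dye-term error was only the scatter of spots within slides. For day 9 against day 3 the probes at least 2-fold different, 232 in the main setting, were 142 with saturated probes left out and 249 to 491 without each slide in turn. The authors' table gave 816, 268 and 783 for the 3 comparisons. These are all the values it lists, since as read here none can be under 2-fold. The cause of the shifts in the other settings was not tested.

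List medians were taken to have moved when they shifted by more than 1 residual SD between slides. Without probes with any saturated spot, medians for day 9 against day 0 became -0.26 (fox cluster), 0.12 (oxidases) and 0.16 (metal resistance). For day 9 against day 3 they became -1.12 (oxidases) and -0.42 (CO2 fixation), and for metal resistance at day 3 the median turned to -0.33, because 1 of 3 members was left. Metal resistance at day 3 was 2.72 with print-tip loess, 2.69 with mean foreground and 4.03 without dim probes. At day 9 against day 3 it was -0.49 without dim probes. At day 9 against day 0 it was 2.99 with median centring, 3.01 with print-tip loess and 2.79 with mean foreground. Without each slide in turn the medians ran from 1.14 to 1.69 (oxidases, day 3), -0.10 to 0.46 (CO2 fixation, day 3), -1.41 to -0.52 (CO2 fixation, day 9 against day 0) and 2.75 to 3.78 (metal resistance, day 9 against day 0). Beyond members left out, the cause was not tested. The SD of the loop sums was 0.72 to 0.81 with the settings run for it (no background correction, median centring, Aquantile, dim probes left out).

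For 77 pairs of gene and comparison printed by the rule, 1031 of 1100 tested values kept side and direction. With saturated probes left out, 24 pairs kept theirs and 2 gained a call. The rest of the 77 pairs rest on probes with a saturated spot and were not tested there. The others lost (32) or gained (37) a call, and none reversed. Aquantile, both dim-probe rules and changes of test unit or variance model kept the main differences, so could reverse nothing. Of uncalled values, 3 changed sign. Of 299 values with no test, 115 moved by more than 1 SD. Weak signal limits most clearly the 384 probes above the empty spots on neither slide of some condition. Only 1079 of 2328 probes stood above them on both slides of every condition.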

Other observations

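The tests on neighbouring probe numbers, on the block and list lower at day 9 and on the scale of the authors' deposited table were chosen only after the results were seen. Among 57 probes whose names contain nc_mse, a term the files do not explain, 11 were higher and 1 lower at day 3 against day 0. At day 9 against day 0, 12 were higher and none lower in the limma fit. Probe nc_mse1603 was 26.2-fold higher (log2 4.71 ± 0.30 SE) and nc_mse0351 20.4-fold higher at day 9 against day 0.

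Calls clustered along the probe numbers. From day 0 to day 3, 22 runs of at least 4 successive numbers were called the same way, the longest of 11, while 1000 shuffles of the numbers gave at most 7 runs. Against day 0, day 9 also gave 22 runs, with at most 5 in shuffles, and day 9 against day 3 gave 1 run, as many as the highest shuffle.

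Differences from day 0 to day 3 correlated at r = 0.417 over 2226 pairs of neighbouring numbers. Shared print position is argued against, since r was 0.43 over the 2167 pairs printed in different blocks and 0.04 over print neighbours with distant numbers. A trend over long stretches is argued against as the whole cause, since r fell to 0.12 at a distance of 20 numbers. Joint transcription of neighbouring genes may contribute, as a hypothesis, but no biological explanation was tested. Similar sequence in neighbouring probes stays open.

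The block Msed_0944 to Msed_0950 had a median of -2.09 and the CO2 fixation list of -1.10 at day 9 against day 3. A single slide is argued against as the cause, since the higher of the medians was -0.97 without the day 9 and day 3 slide. Without either of the other slides it was -1.19, the same in both, since both take the difference from the day 9 and day 3 slide. Loess of bright spots is argued against too, since with median centring the higher median was -1.21. Saturation is argued against as the source of the falls, since no member had a saturated day 9 spot on the day 9 and day 3 slide, where saturation at day 3 only shrinks a fall, and the higher median on that slide with median centring was -1.13. Open are the time on mineral, differences between cultures, which pooled RNA cannot separate from it, and whether the fall extends over the CO2 fixation list, whose 8 members without any saturated spot had a median of -0.42.

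The authors' deposited table lists 115 genes at 0 for days 0 and 3, yet these had a median absolute fitted difference of 0.789 on the log2 scale, which plain log2 fold changes would not give. Read as the log2 of log2 fold changes, the table's values for days 0 and 3 had a slope of 1.01 on the fitted differences and r = 0.973. As deposited, the slope was 0.421 and r was 0.925, so the slope and not the correlation separates the readings. The smallest size so read was 1, but undoing the log2 in this way cannot give a smaller one. That minimum is thus no evidence for the reading or for a 2-fold limit in the table. A second log2 taken before deposit is consistent with these values. This reading was found from the same slides it is compared with.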
